A study of Mus musculus with 48 samples.

How the data were processed

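The series holds RNA-seq and ribosome profiling of wild type and Mettl14 knockout mouse embryonic stem cells, grown per the labels in LIF with 2i on gelatin and used at passages 24 to 28. Per the labels the cells were unstressed, heated at 42 °C for 30 min, or heated and returned to 37 °C for 1 h, with 4 libraries per condition and assay (48 libraries in 12 groups). Per the labels 5% of the lysate went to RNA-seq after ribosomal RNA depletion with a directional kit, and the rest was used for footprints. Per the submitters' processing notes reads were aligned with STAR to mm10 and differential expression was computed with DESeq2; their versions, the counting of footprints and the tool behind the tables of translational efficiency are not given in the sources used here.

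The deposited count tables and the deposited files per sample hold raw counts per gene, reads overlapping mRNA for RNA-seq and reads in coding sequences for footprints. The 2 kinds of file were compared in every cell and 0 differed. The authors' deposited result tables hold log2 fold changes with a p value and an adjusted p value of each gene for wild type heat shock and 1 h recovery against no stress (RNA) and for the genotypes without stress and at recovery (translational efficiency). The deposited counts use 54146 Ensembl identifiers, of which 54079 were matched to GENCODE M21 without the version and 52480 with it. RNA-seq counts without regard to strand were used, and the files per sample also give both strands, of which the second held 94.3% of stranded reads on average. Each file also lists reads that name no gene. Unique reads outside genes were 47.1% in wild type no stress RNA library 1, 24.2 and 37.8% in knockout recovery RNA libraries 3 and 4, between 56.3 and 68.7% in the other RNA libraries, and between 46.7 and 98.0% in the footprint libraries. These reads were left out of all totals.

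Groups follow the titles. All 24 RNA-seq libraries entered a single fit with 6 groups. Footprints were fitted with the 21 libraries that the sample descriptions list for the deposited tables, together with all heat shock libraries, so that knockout no stress library 4 and knockout recovery libraries 1 and 2 were left out. Translational efficiency was tested as the interaction of assay with the comparison in the 42 libraries of the same samples, for genes passing the filter in both assays. Tests were edgeR 4.0.16 quasi-likelihood F-tests (robust, TMM scaling, filterByExpr with a minimum count of 10, prior count 0.125 for fold changes) in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. The filter kept 19994 genes in RNA, 1956 in footprints and 1886 in both. The common biological coefficient of variation was 0.281 in RNA, 0.864 in footprints and 0.450 in the joint fit. CPM values use TMM scaling unless total counts are named, and total counts for footprints.

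The 21 gene lists, written down before the data were examined along with the comparisons, tests, the settings to vary and the rule for naming genes, were cytosolic heat shock chaperones, endoplasmic reticulum unfolded protein response, integrated stress response, immediate early genes, naive pluripotency, primed pluripotency and germ layers, m6A writers, erasers and readers, stress granule proteins, 5'TOP translation machinery, p53 targets, NRF2 targets, the 2-cell-like state, germline and meiosis, type I interferon response, histones, mitochondrially encoded mRNAs, cholesterol biosynthesis, glycolysis and hypoxia, and markers of fibroblasts, primitive endoderm and trophoblast. Lists were tested with camera on the edgeR fit at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Genes of a list were also adjusted over the list alone. By the rule, the text names Mettl14 everywhere, genes among the 8 largest rises and 8 largest falls of a comparison that passed the test with no overlap between groups and a mean count of at least 100 in RNA or 20 in footprints, up to 4 genes per list with the lowest p, all passing m6A genes between genotypes, and any such gene again in other comparisons. The genes named are a part of those the rule gives; they were picked within the rule after the values were seen, mostly for calls that do not rest on a single library. Some genes that the rule allows are not reported here.

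The depth of each library is given with the results. A count of 0 is reported as below 3 counts per library, or 3 counts over the pooled group for translational efficiency, and shares carry Clopper-Pearson exact 95% intervals. Tested on simulated data, where 100 genes were changed 2-fold and 100 changed 4-fold, edgeR recovered 32 and 71% in RNA with 3 of 19794 unchanged genes called, 0 and 0% in wild type heat shock footprints, and 10 and 50% in translational efficiency with 5 of 1686 called. DESeq2 recovered 46 and 78%, 0 and 6%, and 10 and 39%. The simulated libraries differed only in depth, each gene's spread and the planted changes. Their share of false calls may so understate that of the real libraries, which may differ in other ways.

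The labels do not say whether equal title numbers mark samples handled together. This was checked from correlations across genes of the libraries' deviations from their group means: libraries of equal number correlated at 0.19 to 0.47 between wild type no stress and recovery, at 0.14 to 0.56 between wild type and knockout heat shock, and at 0.26 to 0.44 between knockout heat shock and recovery. Between wild type no stress and knockout recovery they correlated at -0.54 to -0.14, so what the numbers mark is not settled. With a replicate block wild type recovery against no stress had 29 genes up and 36 down and the genotypes at heat shock 1257 up and 838 down, near the counts without it, which the report gives.

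Settings tried as planned were DESeq2 1.42.0, DESeq2's median-ratio size factors in edgeR, total counts, no filter on low counts, the compared groups alone, a replicate block, leaving out each replicate, and for footprints all 24 libraries, dropping libraries under 0.25 of the median total (wild type heat shock 2 and 4 and knockout recovery 2), a block per sample and limma voom with quality weights. Chosen after seeing the data were the share of reads outside genes as a covariate, strand-specific counts, title numbers 1 and 2 or 3 and 4 alone, leaving out wild type no stress RNA library 1 with knockout recovery libraries 3 and 4, and leaving out 4 wild type samples chosen from Hspa1a and Egr1 in each library: no stress 3 and 4, with Hspa1a at 99.7 and Egr1 at 63.3 CPM, and recovery 1 and 2, with both under 2 CPM by total counts. In the summed heat shock transcripts no stress 4 (393 CPM) lay near no stress 1 (330 CPM). The set without these 4 was also run for the wild type stress comparisons and is not given there, nor for chaperones and immediate early genes between the genotypes, because it would choose samples by the outcome compared.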

Results

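RNA-seq and ribosome profiling were carried out on wild type and Mettl14 knockout mouse embryonic stem cells. Mettl14 encodes a subunit of the methyltransferase complex that writes N6-methyladenosine (m6A) on mRNA. Cells of both genotypes were left unstressed, were heated at 42 °C for 30 min, or were heated and then returned to 37 °C for 1 h, and each of these 6 conditions was represented by 4 RNA-seq and 4 footprint libraries. The 48 libraries so form 12 groups, and the labels do not say whether the replicates were separate cultures. The design addresses how the transcriptome and translation of the cells respond to heat with and without Mettl14.

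The RNA-seq libraries held between 3537195 and 7570152 reads in genes. Wild type no stress libraries 1 to 4 held 3537195, 7277363, 6329440 and 6365076, wild type heat shock libraries 6433568, 6981441, 7289852 and 7347580, and wild type 1 h recovery libraries 7059443, 7210223, 6656444 and 6281685. Knockout no stress libraries held 7147362, 7549695, 7066427 and 6913755, knockout heat shock libraries 6291415, 5816165, 6975446 and 7293518, and knockout 1 h recovery libraries 6670917, 6557037, 6303013 and 7570152. The footprint libraries were far shallower, between 6557 and 828094 footprints in coding sequences. Wild type no stress libraries 1 to 4 held 94143, 331256, 228252 and 110495 footprints, heat shock libraries 16225, 8862, 33709 and 6557, and 1 h recovery libraries 22990, 358238, 828094 and 42366. Knockout no stress libraries held 205823, 81118, 32187 and 94531, heat shock libraries 37656, 10299, 46966 and 17550, and 1 h recovery libraries 19488, 9092, 43891 and 27964. A gene with no read in a library is below 3 counts, which is 0.848 CPM (reads of a gene scaled to the library) in the shallowest RNA-seq library and 457.53 CPM in the shallowest footprint library. These floors, and all intervals of shares, cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

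Values given after a gene are log2 fold changes ± SE from edgeR with 4 libraries per group, and a gene is said to rise or fall, or to be higher or lower, when its adjusted p was under 0.05. List tests give the adjusted p of camera with a preset correlation and, after it, the adjusted p with an estimated correlation. Genomic positions refer to mm10.

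Mettl14 (ENSMUSG00000028114.16, chromosome 3, 123368297 to 123386108, minus strand) stood at 51.4 ± 8.61 CPM (SD, n = 4) in unstressed wild type RNA, at 62.7 ± 8.10 CPM after heat shock and at 57.8 ± 2.97 CPM after 1 h of recovery. In the knockout the corresponding levels were 11.1 ± 0.975, 14.8 ± 3.14 and 11.8 ± 2.21 CPM. Every knockout library was below every wild type library. Mettl14 RNA was lower in the knockout by -2.21 ± 0.18 without stress (adjusted p = 6.9e-09), by -2.09 ± 0.18 after heat shock (adjusted p = 2.3e-08) and by -2.29 ± 0.18 after recovery (adjusted p = 6.1e-09). No change on heat passed the test in either genotype. It was 0.28 ± 0.17 (adjusted p = 0.66) at heat shock and 0.16 ± 0.17 (adjusted p = 0.86) at recovery in wild type, and 0.41 ± 0.18 (adjusted p = 0.36) and 0.08 ± 0.18 (adjusted p = 0.83) in the knockout.

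**Figure D1:**
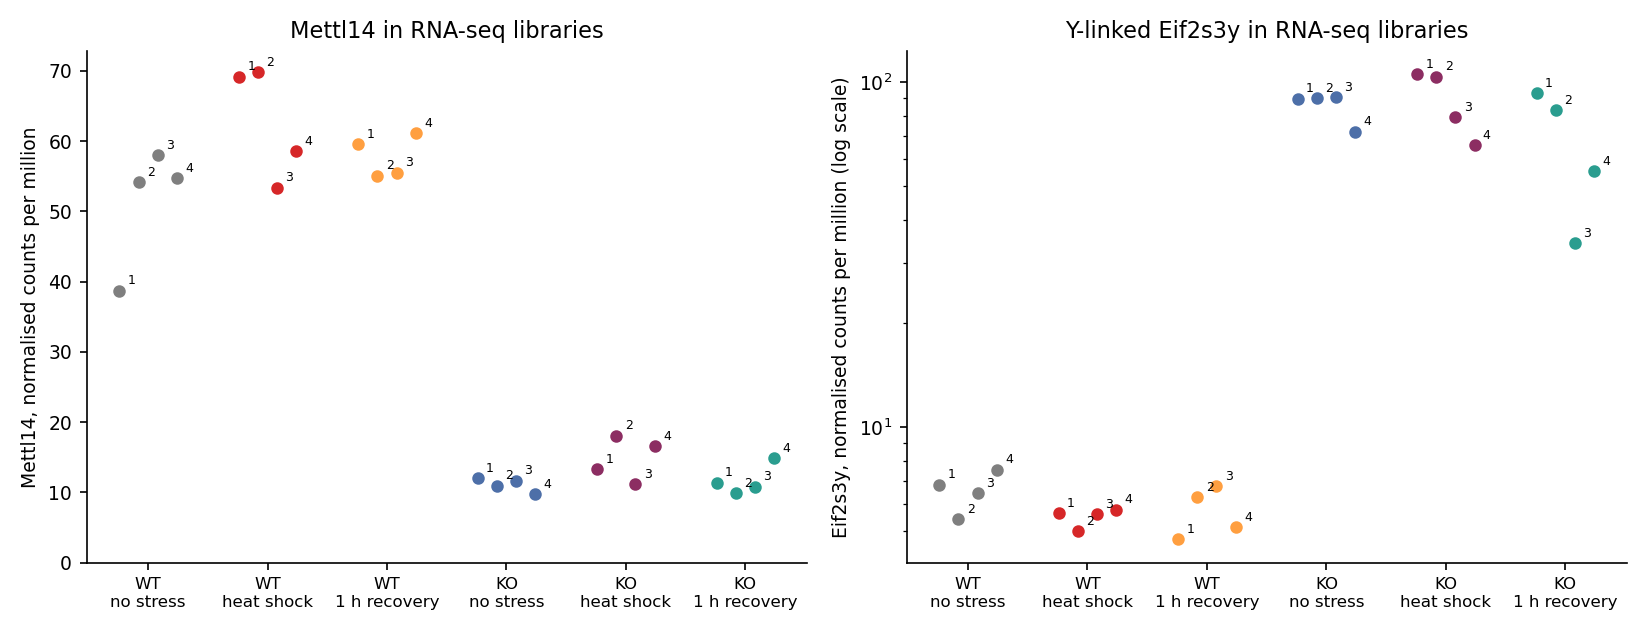
Mettl14 (left) and the Y-linked gene Eif2s3y (right, log axis) in each of the 24 RNA-seq libraries, in CPM, by genotype and stress. Each point is a library, and small digits are the replicate numbers. As means of 4 libraries, Mettl14 stood at 51.4 CPM in unstressed wild type and 11.1 CPM in the unstressed knockout, and Eif2s3y at 6.55 and 85.6 CPM.

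In knockout cells 4 of 33 immediate early genes and 0 of 30 chaperones passed the test at heat shock. The fit takes its spread from the wild type libraries as well. By total counts Hspa1a lay between 0.530 and 1.30 CPM in the unstressed knockout libraries and between 34.3 and 62.4 CPM after heat shock. The 0 so does not show that chaperones failed to respond. Egr1 (chromosome 18, 34859823 to 34864984), an immediate early transcription factor, rose by 6.48 ± 1.18 (adjusted p = 0.024), from 0.645 ± 0.345 to 59.9 ± 23.7 CPM. Its relatives Egr3 and Egr2 rose by 5.47 ± 1.00 and 3.51 ± 0.71, and Fos (chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, rose by 3.81 ± 0.69. Apc2 rose by 2.18 ± 0.37, the cilium gene Invs by 1.10 ± 0.22, the actin regulator Wdr1 by 0.77 ± 0.15, and Slbp, whose product binds the stem loop of histone mRNAs, by 0.74 ± 0.12. Of the reads at Apc2 15.0% and at Invs 22.2% lay on the gene's own strand, and by strand-specific counts Apc2 (1.56), Invs (0.40) and Egr2 (5.14) were not called. All 8 of these calls ended without knockout no stress replicate 1, 2 or 4 or heat shock replicate 3, and those of Egr1, Egr2, Egr3, Fos, Invs and Wdr1 also without no stress replicate 3 or heat shock replicate 1 or 2. The fold changes were then 6.19 to 6.70 for Egr1, 5.18 to 6.997 for Egr3, 3.26 to 3.77 for Egr2, 3.69 to 4.06 for Fos and 2.09 to 2.28 for Apc2. Of 33 immediate early genes 30 had a positive change, 4 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.2e-12, and adjusted p = 0.14 with an estimated correlation). Of 30 cytosolic heat shock chaperones 24 had a positive change and none passed the test over all genes, while 11 rose adjusted over the list alone (camera adjusted p = 3.1e-06, and adjusted p = 0.57 with an estimated correlation). The inducible Hsp70 gene Hspa1a (chromosome 17, 34969190 to 34972156) had a fold change of 5.36 ± 1.30 (adjusted p = 0.11) and its near-identical copy Hspa1b of 3.88 ± 0.99 (adjusted p = 0.12); reads of these copies cannot be assigned with certainty. NRF2 targets (camera adjusted p = 0.0015, and adjusted p = 0.57 with an estimated correlation) and glycolysis genes (camera adjusted p = 0.0041, and adjusted p = 0.61 with an estimated correlation) were shifted down as lists.

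In all, 22 of 19994 genes rose and 0 fell in the knockout at heat shock; 2496 had an unadjusted p under 0.05, where 999.7 would be so by chance, and DESeq2 called 280. The count was 0 without knockout heat shock replicate 3 or knockout no stress replicates 1, 2 or 4, 5 without no stress replicate 3, 6 without heat shock replicate 2 and 11 without heat shock replicate 1. With heat shock and no stress knockout libraries fitted alone 1604 genes rose and 828 fell, and without 4 wild type samples chosen from Hspa1a and Egr1, which share only the estimate of spread, 79 rose and 1 fell.

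After 1 h of recovery 7 genes rose and 7 fell in the knockout. Egr1 was up by 7.06 ± 1.19 over no stress (adjusted p = 0.016) at 89.7 ± 51.2 CPM, Fos by 4.26 ± 0.69, Egr2 by 4.10 ± 0.72 and Apc2 by 2.35 ± 0.37. Atf3, a stress-induced transcription factor, rose by 1.89 ± 0.37. Msi2, which encodes an RNA-binding protein, fell by 0.82 and the Mediator kinase gene Cdk8 fell by 0.61. Egr1 (then 6.57 to 7.31), Fos (3.83 to 4.54) and Egr2 (3.12 to 4.39) lost their calls without any of the 4 no stress libraries or recovery replicate 4. Apc2, with 15.0% of its reads on its own strand, lost its call without no stress replicate 1 or 2 (2.28 to 2.29). By strand-specific counts Apc2 (0.73), Egr2 (5.69), Atf3 (1.92), Msi2 (-0.79) and Cdk8 (-0.59) were not called. Cdk8 (-0.61 to -0.53) did so without any no stress library or recovery replicate 3 or 4, and Atf3 (1.71 to 2.05) and Msi2 (-0.85 to -0.65) in addition without recovery replicate 2 or 3. Of the 33 immediate early genes 4 rose, or 21 adjusted over the list alone (camera adjusted p = 9.6e-18); this list kept its call with an estimated correlation (adjusted p = 0.038). None of the 30 chaperones passed over all genes, with a spread taken from the wild type libraries as well. Of them 15 rose adjusted over the list alone (camera adjusted p = 1.8e-11, and adjusted p = 0.15 with an estimated correlation). Hspa1a had a change of 5.87 ± 1.31 (adjusted p = 0.064), Hspb1 of 0.82 (adjusted p = 0.077) and Dnajb1 of 1.17 (adjusted p = 0.083). Of 25 targets of the integrated stress response 24 had a positive change, 1 (Atf3) rose, or 2 adjusted over the list alone (camera adjusted p = 1.8e-06, and adjusted p = 0.42 with an estimated correlation). Replication-dependent histone genes were positive in 50 of 53 cases (camera adjusted p = 0.00052, and adjusted p = 0.66 with an estimated correlation). They turn down when the 3 libraries with the fewest reads outside genes are left out. Among these are knockout recovery libraries 3 and 4, with 24.2 and 37.8% of unique reads outside genes. Trophoblast markers, a sign of other cells, were positive in 12 of 13 cases and 5 rose adjusted over the list alone (camera adjusted p = 0.0051, and adjusted p = 0.42 with an estimated correlation). The calls of the integrated stress response and trophoblast lists end without the same 3 libraries.

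The split of 7 and 7 among 19994 genes was 4 and 2 with DESeq2's size factors, 6 and 2 with total counts, 36 and 45 with a replicate block and 258 and 319 by DESeq2, and 87 genes rose and 31 fell without the 4 wild type samples. The count was 626 without knockout recovery replicate 1 and 29 without recovery replicate 2, and it was 2 without recovery replicate 4 or no stress replicate 3, 1 without no stress replicates 1 or 2 and 3 without no stress replicate 4.

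In wild type cells edgeR called 0 of 19994 genes at heat shock, with 1733 at an unadjusted p under 0.05, where 999.7 would be so by chance, and a lowest adjusted p of 0.258. DESeq2 called 9, the fit with the share of reads outside genes as a covariate 80 and that without the 3 libraries that stand apart in this share 122. As a list, the 5'TOP translation machinery, ribosomal proteins and translation factors whose mRNAs start with an oligopyrimidine tract, was shifted down: 8 of 91 genes had a positive change and 13 fell adjusted over the list alone (camera adjusted p = 2.3e-13, and adjusted p = 0.29 with an estimated correlation). Rps6 had a change of -1.59 ± 0.40 (adjusted p = 0.39) and Rpl12 of -0.85, though reads of ribosomal protein genes are shared with pseudogenes. Chaperones were positive in 22 of 30 cases, 0 passed in either adjustment (camera adjusted p = 0.031, and adjusted p = 0.79 with an estimated correlation), and Hsp90aa1 had a change of 0.36 and Ahsa1 of 0.34. Histones were shifted down (camera adjusted p = 0.00022, and adjusted p = 0.79 with an estimated correlation).

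The wild type libraries labelled no stress and 1 h recovery did not separate by heat shock transcripts. By total counts, Hspa1a stood at 9.33, 0.275, 99.7 and 11.5 CPM in wild type no stress RNA libraries 1 to 4, at 19.3, 46.8, 32.8 and 38.5 CPM after heat shock, and at 1.98, 0.555, 143 and 64.5 CPM in the 1 h recovery libraries. In the knockout it stayed between 0.530 and 1.30 CPM without stress, 34.3 and 62.4 CPM after heat shock, and 37.9 and 125 CPM after recovery. Footprints of Hspa1a, Hspa1b, Hsph1 and Dnajb1 summed to between 350.5 and 605 CPM in the wild type no stress libraries and to 1348, 1474, 2169 and 401 CPM in the 1 h recovery libraries. Comparisons that use these RNA libraries are therefore given by label, and those of the knockout and of the genotypes also without wild type no stress libraries 3 and 4 and 1 h recovery libraries 1 and 2. These 4 were chosen from Hspa1a and Egr1, of which Egr1 stood at 63.3 CPM in no stress library 4. Within title numbers 1 and 2 the heat shock comparison of wild type called 330 genes (202 up) and within numbers 3 and 4 it called 2321 (1066 up), against 0 in the pooled fit.

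**Figure D2:**
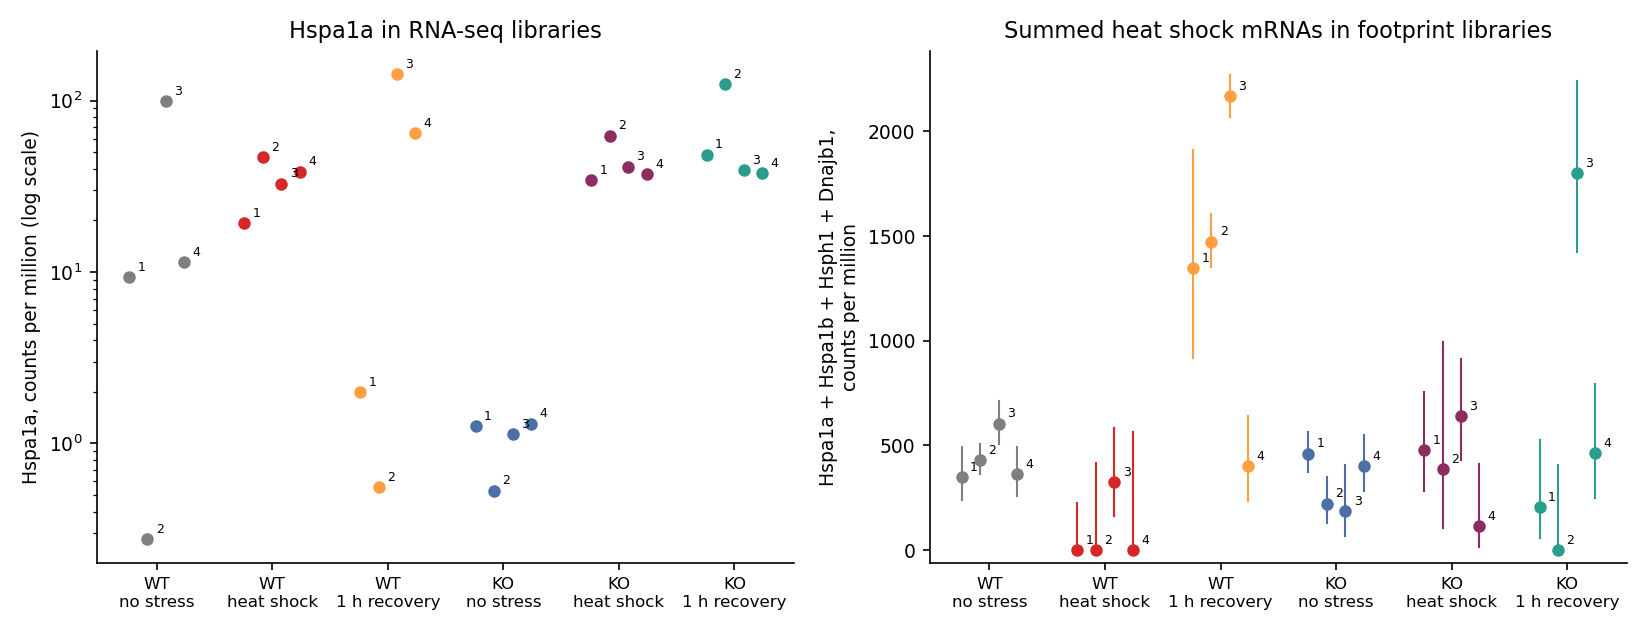
Hspa1a in each RNA-seq library (left, CPM, log axis) and the summed CPM of Hspa1a, Hspa1b, Hsph1 and Dnajb1 in each footprint library with exact 95% binomial intervals (right); small digits are the replicate numbers. In wild type RNA, no stress library 3 stood at 99.7 CPM and recovery library 2 at 0.555 CPM, while in the knockout all heated libraries were above 34 CPM.

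Between wild type libraries labelled 1 h recovery and no stress, Lefty1 (chromosome 1, 180935022 to 180938400) and Lefty2, secreted inhibitors of Nodal, changed by -3.33 ± 0.53 (adjusted p = 0.0042) and -2.44 ± 0.38. Without a library Lefty1 ran from -3.67 to -2.73. It lay at 91.0 ± 66.1 CPM in the no stress and 8.90 ± 4.99 CPM in the recovery libraries. The slit diaphragm genes Nphs1 and Kirrel2 changed by -1.95 ± 0.23 and -2.18, the phospholipase gene Liph by -1.72, and the glycolytic genes Pdk1 and Pfkp by -1.20 ± 0.21 and -1.005 ± 0.21. Gnal rose by 1.46 ± 0.23, the ganglioside synthase gene St8sia1 by 1.43, the guidance receptor gene Sema5a by 1.37 ± 0.19, Gata3, a trophoblast transcription factor, by 1.36 ± 0.25, and Perp, a p53 target, by 1.15 ± 0.25. Of 25 p53 targets 1 rose, or 10 adjusted over the list alone (camera adjusted p = 4.3e-06, and adjusted p = 0.30 with an estimated correlation). Primed pluripotency and germ layer genes fell in 2 of 24 cases, or 3 adjusted over the list alone (camera adjusted p = 6.6e-05, and adjusted p = 0.18 with an estimated correlation), and glycolysis and hypoxia genes in 2 of 27, or 4 (camera adjusted p = 0.002, and adjusted p = 0.51 with an estimated correlation). None of 14 genes of the 2-cell-like state passed over all genes, while 8 fell adjusted over the list alone (camera adjusted p = 3.9e-06, and adjusted p = 0.30 with an estimated correlation). Zscan4e, of a family of near-identical copies, had a change of -1.86 (adjusted p = 0.27). All 53 histone genes had a negative change (camera adjusted p = 1.4e-08, and adjusted p = 0.51 with an estimated correlation) and all 7 mitochondrially encoded mRNAs a positive one (camera adjusted p = 4.3e-06, and adjusted p = 0.32 with an estimated correlation). Mitochondrially encoded genes took 0.47, 1.79, 1.07 and 1.66% of counts in no stress libraries 1 to 4 and 2.04, 2.05, 2.05 and 2.56% in the recovery libraries.

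Here 28 genes rose and 35 fell of 19994. The count was 12 without wild type recovery replicate 1 or 2, 13 without no stress replicate 4, 25 without no stress replicate 1, and 39 and 40 without recovery replicates 3 and 4. Lefty1, Lefty2, Nphs1, Kirrel2, Gnal, St8sia1 and Sema5a kept their calls without any single library in the fits run. Liph (then -1.73 to -1.63), Pdk1 (-1.20 to -0.99), Gata3 (1.26 to 1.37), Pfkp (-1.07 to -0.95) and Perp (0.97 to 1.27) lost theirs without recovery replicate 1 or 2 or no stress replicate 4. Gata3 and Perp did so also without no stress replicate 2, Perp and Pfkp also without no stress replicate 1 or 3 or recovery replicate 4, and Pfkp without recovery replicate 3. With the compared libraries alone 12 genes were called and by DESeq2 209. Against heat shock, 8 genes rose and 0 fell in the wild type recovery libraries, among them Sema5a by 1.08, the natriuretic peptide receptor gene Npr3 by 0.91 and the adhesion gene Ncam1 by 0.90. A replicate block or total counts left 0 calls there, as did leaving out recovery replicate 2 or 4 or heat shock replicate 1, 2 or 3, while 1 was called without recovery replicate 1 and 14 were called without recovery replicate 3. There 1377 genes had an unadjusted p under 0.05 and DESeq2 called 101. The calls of Sema5a (then 0.93 to 1.22), Npr3 (0.83 to 0.91) and Ncam1 (0.79 to 1.01) ended without recovery replicate 1, 2 or 4 or heat shock replicate 1, 2 or 3, and that of Ncam1 also without heat shock replicate 4. Endoplasmic reticulum unfolded protein response genes were positive in 19 of 20 cases in that comparison (camera adjusted p = 6.7e-09, and adjusted p = 0.26 with an estimated correlation).

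Without stress, knockout and wild type cells differed in 3594 genes, of which 2021 were higher and 1573 lower in the knockout. The Y-linked histone demethylase gene Kdm5d (chromosome Y, 897788 to 956786) was higher by 6.11 ± 0.42, at 44.3 against 0.740 CPM, and the Y-linked translation and helicase genes Eif2s3y and Ddx3y by 3.71 and 3.56. The endocytic adaptor gene Dab2 (chromosome 15, 6299788 to 6440712), an endoderm marker, was higher by 3.87 ± 0.37, at 47.9 ± 3.75 against 3.17 ± 1.78 CPM, and the matrix gene Fbn2 by 3.54. So were Nhsl2 (4.39), Pof1b (3.97) and Acpp (3.48). Nhsl2 and Pof1b are X-linked, and over 517 X-linked genes the median was 0.31, with 153 higher and 20 lower. The transcription factor gene Klf12 (chromosome 14, 99870632 to 100284679) was lower by -3.65 ± 0.33, at 2.70 ± 0.839 against 33.8 ± 6.37 CPM, as were Sept1 (-3.11), the signalling gene Irak3 (-3.07), the solute carrier gene Slc5a11 (-2.90) and Kirrel2 (-2.86).

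Dusp6, which encodes an ERK phosphatase, was lower in the unstressed knockout by -3.23, and Egr1, Fos and Ier2 by -5.10 ± 1.18, -2.95 and -1.66. In wild type no stress libraries 1 to 4 Egr1 stood at 4.24, 1.37, 22.0 and 63.3 CPM by total counts, and within title numbers 1 and 2 Egr1 (-1.73), Fos (-1.19) and Hspa1a (-2.28) were not called. Without a library Egr1 ran from -5.50 to -3.86 and Fos from -3.27 to -2.15. Of 33 immediate early genes 11 were lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.68 with an estimated correlation). Of 30 naive pluripotency genes 12 were lower and 2 higher, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.68 with an estimated correlation): Klf5 by -2.25, Nr0b1 by -1.94 and Sox2 by -0.63 against Dppa3 by 3.01. Primed and germ layer genes went both ways (4 higher and 5 lower of 24, or 5 and 5 adjusted over the list alone). Lefty1 lay at -2.82 (-3.18 to -2.21 without a library) and the neural gene Sox1 at -1.65. Chaperones were lower in 7 and higher in 2 of 30 cases, or 8 and 3 adjusted over the list alone, among them Hspa1a at -4.87 ± 1.30 and Hspb1 at -0.77 against Cryab at 1.97. The TOP translation machinery was lower in 15 of 91 cases and higher in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 4.1e-06, and adjusted p = 0.68 with an estimated correlation). Rps18 lay at -0.71, Rpl10a at -0.97 and Rpl27 at -1.09. Histones were lower in 16 of 53 cases, or 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.2e-07, and adjusted p = 0.68 with an estimated correlation). Hist1h2bh lay at -1.95 and Hist1h2bk at -1.56 (-1.75 to -1.03 without a library). Cholesterol synthesis genes were lower in 7 of 24 cases, or 10 adjusted over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.68 with an estimated correlation). Sqle lay at -0.80, Lss at -0.72 and Hmgcs1 at -0.60. The 2-cell-like genes were higher in 4 of 14 cases, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.68 with an estimated correlation). Usp17lb lay at 2.73 and Usp17le at 2.33, members of a family of near-identical copies.

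Among the 23 m6A writers, erasers and readers besides these groups, 4 were higher and 4 lower without stress, or 4 and 5 adjusted over the list alone. The reader gene Ythdf2 was higher by 0.98, the writer subunit genes Cbll1 and Virma by 0.75 and 0.67 and the reader gene Ythdf1 by 0.43, while Mettl14, the catalytic subunit gene Mettl3 (-0.37), Hnrnpc (-0.44) and Hnrnpa2b1 (-0.30) were lower. The call of Mettl3 ended without wild type replicate 2 or 4 or knockout replicate 1, 2 or 3 (then -0.38 to -0.35). That of Ythdf1 ended without wild type replicate 1, 2 or 4 or knockout replicate 1 or 2 (0.38 to 0.43), that of Hnrnpc without wild type replicate 1 or knockout replicate 1, 3 or 4 (-0.43 to -0.30). That of Hnrnpa2b1 ended without wild type replicate 3 or 4 or knockout replicate 1, 2 or 3 (-0.30 to -0.26). Primitive endoderm genes were higher in 4 of 14 cases and lower in 1, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.68 with an estimated correlation). Fibroblast genes were higher in 4 of 13 cases and lower in 3, the same adjusted over the list alone (camera adjusted p = 0.24). Col5a2 lay at 3.14 and Thy1 at 2.04. Trophoblast genes were higher in 2 of 13 cases and lower in 0, the same adjusted over the list alone (camera adjusted p = 0.23). Gata3 lay at 1.37. Without the 4 wild type samples, 928 genes were higher and 1158 lower, 1731 of them called in the full fit in the same direction. With the 2 wild type libraries left, Dppa3 (2.72), Thy1 (1.39), Cbll1 (0.90), Mettl3 (-0.47), Hnrnpa2b1 (-0.32) and Ythdf1 (0.46) were no longer called. Chaperones and immediate early genes are not given for this set, which was chosen by 2 of them. Hspa1a lost its call without wild type no stress replicate 3 alone, at -2.79.

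After heat shock 1330 genes were higher and 912 lower in the knockout. Kdm5d was higher by 6.67, Pof1b by 4.35, Eif2s3y by 4.01, Dab2 and Fbn2 by 3.77 each, and the Y-linked histone demethylase gene Uty by 3.71. Klf12 was lower by -3.52, the phospholipase gene Pla2g1b by -3.48, Gpa33 by -2.38 and Xaf1, an interferon-induced gene, by -2.16. Cholesterol synthesis genes were lower in 9 of 24 cases and higher in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 3e-06, and adjusted p = 0.58 with an estimated correlation). Among them were Lss (-0.80) and Hmgcs1 (-0.70). The 2-cell-like genes were higher in 5 of 14 cases, or 7 adjusted over the list alone (camera adjusted p = 0.00024, and adjusted p = 0.89 with an estimated correlation). Usp17le lay at 2.07 and Zscan4d at 1.70. Histones were lower in 8 of 53 cases in both adjustments (camera adjusted p = 2.2e-07, and adjusted p = 0.94 with an estimated correlation). Hist1h2bh lay at -1.82 and Hist1h1b at -1.28. Naive pluripotency genes were lower in 6 of 30 cases and higher in 1, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.94 with an estimated correlation). Klf5 lay at -1.16. Sox1 stood at -1.90 while Nes, a neural progenitor filament gene, was higher by 1.00. Of the m6A genes 3 were higher and 1 lower, or 4 and 2 adjusted over the list alone: Ythdf2 at 0.82, Rbm15 at 0.60 and Virma at 0.46, against Mettl14. Virma lost its call without wild type replicate 1, 3 or 4 or any knockout replicate (then 0.40 to 0.49) and without the 4 wild type samples (0.44). Of the 30 chaperones 2 were higher and 1 lower, or 2 and 3 adjusted over the list alone. Glycolytic Pfkp (-1.01), Eno1 (-0.70) and Aldoc (-1.41) were lower, in a list with 4 lower and 2 higher of 27, or 5 and 2 adjusted over the list alone.

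After 1 h of recovery 2436 genes were higher and 1534 lower in the knockout. Kdm5d was higher by 5.92, the carbonyl reductase gene Cbr3 by 3.77, Mocos by 3.55, Eif2s3y by 3.54, Dab2 by 3.35 and Fbn2 by 3.34. The citrate transporter gene Slc13a5 was lower by -2.62, the noncoding RNA Lncenc1 by -2.59, Adgrv1 by -2.47, Rapgef3 by -2.26 and Ceacam20 by -2.17. Of 14 genes of the 2-cell-like state 10 were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 9.9e-10, and adjusted p = 0.22 with an estimated correlation). The near-identical copies Usp17le, Usp17lb, Usp17lc and Usp17la stood at 3.55, 3.04, 2.60 and 2.56. NRF2 targets were higher in 10 of 20 cases and lower in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 8.7e-05, and adjusted p = 0.57 with an estimated correlation), with the NADPH-producing enzyme genes Me1 (1.23), Pgd (1.18) and G6pdx (1.11) and the thioredoxin reductase gene Txnrd1 (0.65). Targets of the integrated stress response were higher in 8 of 25 cases, or 10 adjusted over the list alone (camera adjusted p = 0.0003, and adjusted p = 0.57 with an estimated correlation). Atf5 lay at 1.47, the proline synthesis gene Aldh18a1 at 1.35 and the seryl-tRNA synthetase gene Sars at 0.98. Cholesterol synthesis genes were lower in 9 of 24 cases, or 12 adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.57 with an estimated correlation). Hmgcs1 lay at -0.93, Msmo1 at -0.74 and Insig1 at -0.62. Stress granule genes were lower in 10 and higher in 2 of 30 cases, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.57 with an estimated correlation). The poly(A)-binding protein gene Pabpc1 lay at -0.71.

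Of the 30 chaperones 6 were higher and 0 lower at recovery, the same adjusted over the list alone (camera adjusted p = 0.075). The co-chaperone gene Bag3 lay at 1.13 and Hspb8 at 1.02. Transcripts of Hspa1a, Hspa1b, Hsph1 and Dnajb1 summed to 284, 264, 1876 and 691 CPM in wild type recovery libraries 1 to 4 and to between 610 and 1866 CPM in the knockout, and within title numbers 3 and 4 Bag3 (1.22) and Hspb8 (0.96) kept their calls. Immediate early genes were higher in 6 of 33 cases, or 5 adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.57 with an estimated correlation). Rhob lay at 1.42. Naive pluripotency genes were higher in 4 and lower in 5 of 30 cases, or 6 and 6 adjusted over the list alone. Klf2 lay at 1.10 and Klf5 at -1.54. Of 25 p53 targets 7 were lower and 1 higher, or 7 and 2 adjusted over the list alone. Trp53inp1 lay at -0.97, Ccng1 at -0.73 and Zmat3 at -0.68. Germline genes were higher in 6 and lower in 2 of 24 cases, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.047, and adjusted p = 0.57 with an estimated correlation). Rhox6 lay at 3.09 (2.47 to 3.37 without a library). Interferon response genes were higher in 3 and lower in 1 of 18 cases in both adjustments. Oasl1 lay at 3.17. Genes of the m6A list were higher in 4 and lower in 2 of 23 cases in both adjustments. Ythdf2 lay at 0.77. Trophoblast markers were higher in 4 of 13 cases, or 5 adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.57 with an estimated correlation). The keratin genes Krt8 and Krt18 lay at 2.06 and 2.18 (1.37 to 2.35 and 1.35 to 2.55 without a library). Knockout recovery libraries 3 and 4 had fewer reads outside genes than any other library. Without them and wild type no stress library 1 the call of Bag3 remained while those of Krt8 (0.77), Krt18 (0.18), G6pdx (0.55), Sars (0.34) and Hspb8 (0.75) ended. So did those of the germline, immediate early, integrated stress response and trophoblast lists. Without the 4 wild type samples 1119 genes were higher and 529 lower, 1585 of them called in the full fit in the same direction. The germline and trophoblast lists were no longer called. With the compared libraries fitted alone 778 were higher and 367 lower.

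**Figure D3:**
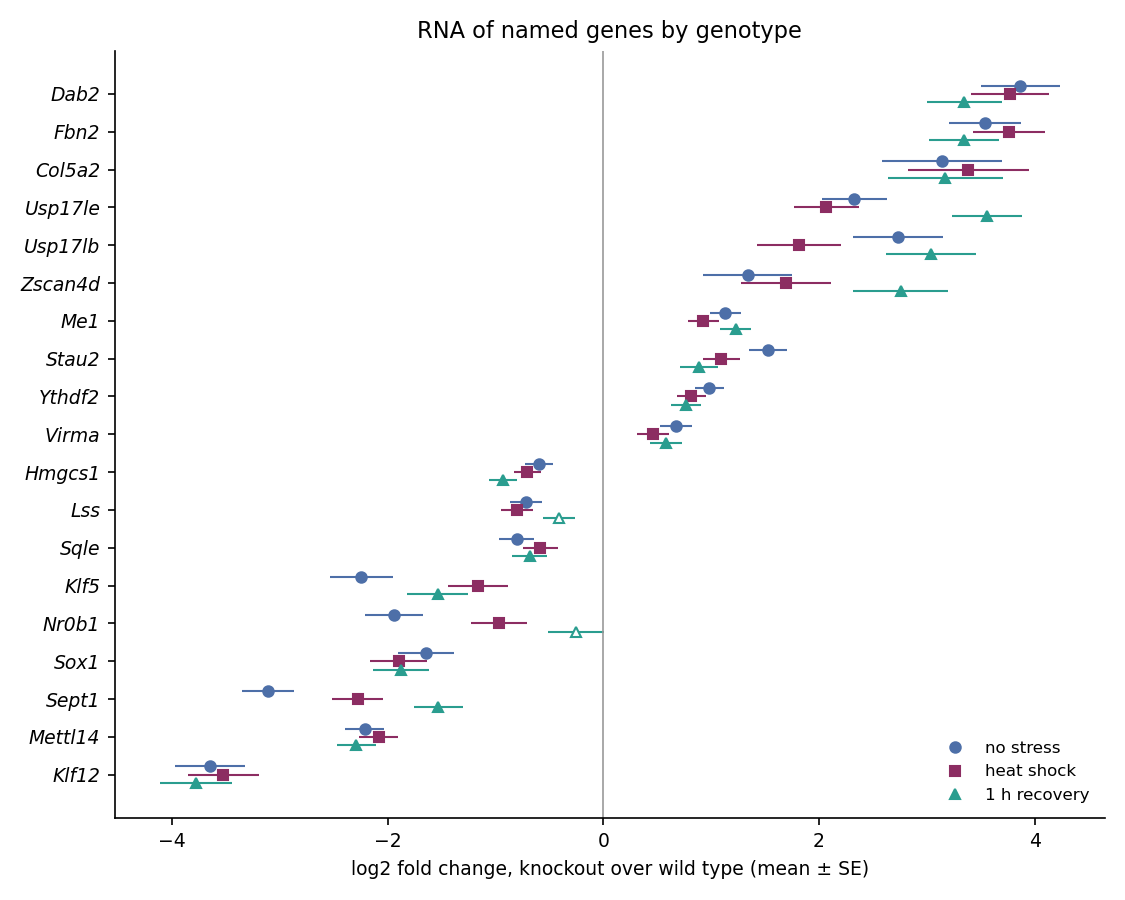
Log2 fold changes of 19 genes, knockout over wild type, without stress, after heat shock and after 1 h of recovery; bars are the SE from edgeR (n = 4 libraries per group) and open markers have an adjusted p of 0.05 or more. Klf12 lies at -3.65 without stress and -3.52 after heat shock, and Mettl14 at -2.21, -2.09 and -2.29 in the order of states given.

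The interaction of genotype and stress asks whether heat changed a gene differently in the knockout. At heat shock 0 genes passed by edgeR, 731 had an unadjusted p under 0.05, fewer than the 999.7 of chance, and DESeq2 called 0. The immediate early genes as a list were shifted toward a more positive change in the knockout (7 positive and 0 negative adjusted over the list alone, camera adjusted p = 2.5e-11, and adjusted p = 0.19 with an estimated correlation). By total counts Egr1 stood at 4.24, 1.37, 22.0 and 63.3 CPM in wild type no stress libraries 1 to 4. It stood at 0.992, 1.25, 37.9 and 28.3 CPM in the wild type recovery libraries. The wild type changes of immediate early genes are so uncertain, and their interactions do not show a stronger response of the knockout. At recovery 26 genes had a more positive change in the knockout and 90 a more negative one. Dusp6 had an interaction of 3.74, Egr1 of 7.46, Fos of 4.29 and Etv4, a transcription factor of ERK signalling, of 1.79, and Nphs1 and Liph stood at 1.76 and 2.24. Among the negative were Gnal (-1.69), Prrg4 (-1.70), Lrrc8b (-1.76) and St8sia1 (-1.59). Dusp6, Etv4 and Prrg4 kept their calls without any single library. All others named here lost theirs without knockout no stress replicate 3. Gnal (then -1.64 to -1.61), Lrrc8b (-1.65 to -1.61), St8sia1 and Fos did so also without wild type recovery replicate 1. Egr1 (6.22 to 7.64) did so without wild type no stress replicate 4, wild type recovery replicate 2 or knockout no stress replicate 4, and Fos (3.48 to 4.55) and St8sia1 (-1.59 to -1.50) without 9 and 7 of the 16 libraries. Of 33 immediate early genes 4 were positive and 0 negative, or 13 and 0 adjusted over the list alone (camera adjusted p = 5.2e-10, and adjusted p = 0.21 with an estimated correlation). All 53 histones were positive (camera adjusted p = 9.8e-10, and adjusted p = 0.40 with an estimated correlation), and the list turned down without the 3 libraries that stand apart in reads outside genes (camera adjusted p = 0.37). Without the 4 wild type samples, which leaves no stress 1 and 2 and recovery 3 and 4 of wild type, 0 genes were called. The interactions of Liph (2.21), Nphs1 (1.86), Etv4 (1.48), Gnal (-1.59) and Prrg4 (-1.49) then stayed near the full fit, and those of Lrrc8b and St8sia1 were -1.35 and -1.04. With total counts 15 were positive and 22 negative. The count was 10 without knockout no stress replicate 3, 23 without replicate 4, 48 and 49 without replicates 1 and 2. It was 18 and 19 without wild type recovery replicates 2 and 1, 38, 54 and 63 without wild type no stress replicates 3, 4 and 1, 58 without knockout recovery replicate 4, and 203, 211 and 226 without wild type no stress replicate 2 and knockout recovery replicates 2 and 1.

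Footprints alone gave few differences at this depth. Mettl14 had 5 footprints in wild type no stress library 1 (53.1 CPM, exact 95% binomial interval 17.2 to 124) and 16 in library 2 (48.3 CPM, 27.6 to 78.4). Knockout no stress libraries 1 to 3 together had 1 in 319128, or 3.13 CPM. Knockout no stress library 4, left out of the fit, had 5 in 94531 (52.9 CPM), at the level of wild type. By edgeR 0 of 1956 genes passed in any of the 4 footprint comparisons. Wild type heat shock against no stress had 630 genes at an unadjusted p under 0.05 and DESeq2 called 955 (46 up). Wild type recovery against no stress had 48 and 0, knockout against wild type without stress 144 and 1, and knockout against wild type at recovery 81 and 0. In wild type heat shock the median of all genes was shifted by -0.99 with TMM scaling, by -2.63 with DESeq2's size factors and by -1.41 with total counts. There 455 genes were called without heat shock replicate 3. Between the genotypes 1 gene was called without knockout no stress replicate 1. Without knockout recovery replicate 3 or 4 that group holds 1 library, so no count is given. Relative to the other genes, 12 chaperones (0 called, 0 up and 5 down adjusted over the list alone, camera adjusted p = 0.011) and 28 genes of the TOP translation machinery (0 called in either adjustment, camera adjusted p = 0.011) were shifted down, each with an adjusted p of 0.66 with an estimated correlation. In the unstressed knockout 11 glycolysis genes were shifted down against wild type (0 called, 2 down adjusted over the list alone, camera adjusted p = 1.9e-05, and adjusted p = 0.65 with an estimated correlation).

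Translational efficiency, the change in footprints beyond the change in RNA, was lower for many genes of wild type cells after heat shock. Ahsa1, a co-chaperone of Hsp90 (adjusted p = 0.001), had 2 footprints over the heat shock libraries, as had the mitochondrial chaperonin gene Hspd1 and the pluripotency gene Nodal, and the growth factor gene Fgf4 had 1. With these counts set to a pooled floor of 3 in 65353 counts (45.9 CPM) they were 15.3-fold, 7.30-fold, 5.06-fold and 7.24-fold lower. A count of 1 or 2 set to 3 is not an upper limit, so the true falls may be smaller. These folds hold for the pooled group alone, since the floor rises to 94.8 CPM without heat shock library 3. Without a library the fitted change of Ahsa1 ran from -5.24 to -3.83 and that of Hspd1 from -4.16 to -2.73. The smallest falls of Nodal and Fgf4 were -2.40 and -3.94. Their lowest fits, -11.8 and -12.5, are as extreme as those of genes with no heat shock footprint (Abce1 -12.8, Dnajb1 -11.1) and give no measured fold. The Hsp70 and Hsp90 adaptor gene Stip1 fell by 2.70 (16 footprints), the pluripotency gene Nanog fell by 2.52 (17), the ribosomal protein gene Rack1 fell by 3.05 (21) and the elongation factor gene Eef1d fell by 2.45 (9). Hmgcs1 fell by 2.81 (5) and the glycolytic gene Gpi1 fell by 2.73 (3). Without a library these changes ran from -4.29 to -2.18 for Stip1, -6.48 to -2.56 for Rack1 and -4.88 to -1.89 for Eef1d. The smallest falls were -2.02 for Nanog, -2.33 for Hmgcs1 and -2.26 for Gpi1. Their lowest fits, -14.4, -13.1 and -12.3, are likewise as extreme as those of genes with no heat shock footprint and give no measured fold. Several genes had no footprint in any heat shock library and are bounded against the same floor. Translational efficiency was at least 9.88-fold lower for the ribosome recycling factor gene Abce1, 8.70-fold for Snrpa1, 6.77-fold for Wdr1, 6.48-fold for Swi5, 5.69-fold for Ctcf and 3.26-fold for Dnajb1. Heat shock library 3 holds 33709 of the counts, and without it these bounds were 5.04-fold, 4.40-fold, 3.47-fold, 3.25-fold, 2.82-fold and 1.74-fold. Among genes that rose were D10Wsu102e by 3.56 ± 1.04 and the fibroblast growth factor receptor gene Fgfr2 by 4.50 ± 1.44. These calls ended without no stress replicate 2 or heat shock replicate 4 (D10Wsu102e, 3.09 to 3.27) and without no stress replicate 3 or heat shock replicate 1 or 2 (Fgfr2, 3.07 to 3.97), and over all libraries left out they ran from 3.09 to 4.41 and 3.07 to 6.74. Of 12 chaperones 6 fell and 0 rose, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.78 with an estimated correlation). Of 8 unfolded protein response genes of the endoplasmic reticulum 5 fell, or 7 adjusted over the list alone. Of 28 genes of the TOP translation machinery 7 fell in both adjustments, and of 18 naive pluripotency genes 7 fell and 2 rose, or 8 and 2 adjusted over the list alone.

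In total 132 of 1886 genes rose and 479 fell in translational efficiency at wild type heat shock, with a median of -2.56 among those that fell, or -2.42 with the 41 that had no heat shock footprint at their bound; 231 of the 479 had at most 3 heat shock footprints over the group. The median of all genes was -1.01 with TMM scaling, -2.42 with DESeq2's size factors, where 65 rose and 947 fell, and -1.22 with total counts, so falls are relative to a scaling that the data do not fix. The heat shock libraries held 6557 to 33709 footprints. Without the libraries under 0.25 of the median total, among them heat shock libraries 2 and 4, 3 genes rose and 2 fell. With the compared libraries alone 66 rose and 89 fell, and with RNA and footprints of equal title number paired as a block 0 were called. The count was 159 without heat shock replicate 4, 242 and 372 without no stress replicates 2 and 3, 343 without heat shock replicate 2 and 945 without heat shock replicate 3. Nanog (-2.02), Nodal (-2.40), Rack1 (-2.56), Hspd1 (-2.73) and Dnajb1 lost their calls without heat shock replicate 4.

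In the other comparisons of translational efficiency 2 genes passed in all. At wild type recovery Ppp1r10 (chromosome 17, 35916434 to 35932283), which encodes a regulatory subunit of protein phosphatase 1, rose by 2.86 ± 0.58 (adjusted p = 0.025). The call ended without no stress replicates 2, 3 or 4 or recovery replicate 1, at 2.61 to 2.90, and 2 genes were called without recovery replicate 2. The 28 genes of the TOP translation machinery were positive in 24 cases there (0 called in either adjustment, camera adjusted p = 3.5e-06, and adjusted p = 0.97 with an estimated correlation). Between the genotypes 0 of 1886 genes passed without stress by edgeR (157 at an unadjusted p under 0.05, of which 113 were higher, 2 by DESeq2 and 0 by limma). After heat shock 0 passed (255, of which 216 were higher, 8 and 0), with a median of all genes of 0.53. At recovery Lemd3 (chromosome 10, 120923413 to 120979332), a gene of the inner nuclear membrane, was higher in the knockout by 3.99 ± 0.81 (adjusted p = 0.023), with 2 knockout libraries in the fit. Without recovery replicate 3 or 4 of the knockout, which leaves 1 library in that group, or 2 or 3 of wild type the change was 3.40 to 3.82. The call ended without recovery replicate 2 or 3 of wild type and without the 4 wild type samples. Counts without a library were 13 without stress (knockout replicate 1). After heat shock they were 193, 11 and 9 (wild type replicate 3 and knockout replicates 2 and 4). At recovery they were 6 and 36 (wild type replicates 1 and 4). Without stress 11 glycolysis genes had a lower translational efficiency in the knockout as a list (0 called, 2 adjusted over the list alone, camera adjusted p = 4.6e-05, and adjusted p = 0.56 with an estimated correlation). At recovery the TOP translation machinery was lower (0 called in either adjustment of 28, camera adjusted p = 1.3e-05, and adjusted p = 0.63 with an estimated correlation).

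The authors' deposited table of wild type 1 h recovery against no stress calls 1189 of 14602 genes (839 up and 350 down), of which 0 were called here by label and 563 had the same sign. Of the 63 genes called here 60 are in the authors' deposited table and 0 are called by both. For wild type heat shock the authors' deposited table calls 9 genes, all up, of which 0 were called here and 6 had the same sign. Across genes, which are not independent replicates, the authors' deposited log2 fold changes were correlated with the edgeR fold changes of the labelled groups. Over 14602 genes r was 0.035 for recovery and -0.013 for heat shock. In a test chosen after the result was seen, mean log2 differences of abundant genes were used instead. The labelled split then gave 0.14 for recovery and 0.15 for heat shock, and a split of the same libraries by title number gave 0.99 and 0.96. Both deposited wild type tables may so set other libraries against each other than the labels do. The lack of shared calls therefore does not test the calls of either side. The authors' deposited tables of translational efficiency call 3 of 6270 genes without stress, all down as coded, and 0 of 7131 at recovery. In the authors' deposited tables the values correlated with the knockout over wild type changes found here at -0.99 and -0.86 across genes, so they are coded as wild type over knockout.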

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

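The tests of the wild type tables against other splits and of unheated recovery samples were chosen after the result was seen, and the rank of the labelled split was predicted after the values of Hspa1a and Egr1 per library had been seen but before the rank was computed.

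A difference between groups drew attention to the interaction of genotype and 1 h recovery, with 116 genes called, and to its named genes: Egr1 (7.46), Fos (4.29), Liph (2.24), Zfp819 (1.81), Etv4 (1.79), Nphs1 (1.76), Nr0b1 (1.69), Ier2 (1.66), Dynlt3 (-1.88), Nhsl2 (-1.80), Lrrc8b (-1.76), Prrg4 (-1.70), Gnal (-1.69), Mipol1 (-1.68), Usf3 (-1.61) and St8sia1 (-1.59). Without the 4 wild type samples chosen from Hspa1a and Egr1 all of these calls end. That leaves 2 wild type libraries per group, of title numbers 1 and 2 against 3 and 4, and Liph (2.21), Nphs1 (1.86), Nr0b1 (1.74), Gnal (-1.59) and Dynlt3 (-1.75) stay near the full fit while Zfp819 (0.96) and Mipol1 (-0.65) do not, so the lost calls do not show on which libraries the 116 rest. For Egr1 and Fos the choice of the samples fixes the outcome. Of 100 splits 4 gave as many genes as the 116, the labelled one among them. 1 of the others called 1380, which points to a structure of the samples besides genotype and stress. Under such a structure the splits cannot exclude chance for the 116.

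The heat shock transcripts of the wild type RNA libraries depart from the no stress and 1 h recovery labels. Among the 35 splits of these 8 libraries the labelled split ranked 23 by the mean log2 difference of the 30 listed chaperones (0.18), while in the knockout it ranked 1 (0.81). The highest wild type split (0.69) exchanges 2 libraries between the groups, so an exchange of RNA labels may be part of the cause; it names no stress libraries 1 and 3 as heated, whereas libraries 3 and 4 were left out above, and the data do not settle which. In Hspa1a, Hspa1b, Hsph1 and Dnajb1, 3 of 4 wild type recovery footprint libraries exceeded every no stress one, against 1 of 4 in RNA. For those 3 this argues against unheated samples, but RNA of equal number may not share them. The authors' deposited table of recovery against no stress correlated across 11691 abundant genes, by mean log2 differences, at 0.14 with the labelled split. With the split of libraries numbered 3 and 4 against those numbered 1 and 2 it correlated at 0.99. For the authors' deposited table of heat shock against no stress these values were 0.15 and 0.96 across 11742 genes. Both tables so follow the numbers more than the labels, and may set other libraries against each other than the labels do.

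The 63 genes called between wild type libraries labelled 1 h recovery and no stress were weighed against recovery from heat shock. Of these, 33.3% (exact 95% interval 22.0 to 46.3) had the same sign in knockout recovery against no stress (48.6% of those that fell and 14.3% of those that rose), which argues against recovery shared by the cell lines if the wild type labels hold, and a response of wild type cells alone was not tested. A shift of the cultures along the difference between the cell lines stays open, with 73.0% (60.3 to 83.4) having the same sign in knockout against wild type heat shock. Both intervals take the genes as independent, which genes measured in the same libraries are not, so they understate the spread. Chance cannot be excluded, since 2 of 35 splits gave as many genes and the split of numbers 1 and 2 against 3 and 4 gave 331, which points to a structure of the samples; among the 8 splits that part all 4 pairs of equal number the labelled split gave 63 and the highest other 0. Within numbers 1 and 2 the comparison called 79 genes and within 3 and 4 it called 32.

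The 611 calls of translational efficiency in wild type heat shock may come in part from background reads in shallow libraries, since 76.8% of the called genes move as footprint CPM moves with falling depth within the other groups (98.5% of those that rose and 70.8% of those that fell, against 73.6% of all 1886 genes). With recovery footprints thinned to the heat shock totals, the median over 10 draws was 0 calls in recovery against no stress, against 1 unthinned. Loss of counts by itself so added no calls. Thinning keeps the expected share of each gene and lowers power. It therefore cannot copy a library that is shallow from the start, and other effects of depth stay open. Of 35 splits only the labelled one gave as many calls in the unpaired fit (highest other 194), and 1 in 35 is the lowest share such splits can reach. The fit that pairs RNA and footprints of equal number calls 0 of 1886 genes. Whether equal numbers share a sample is not settled. Deviations of footprints and RNA of equal number correlated at -0.10, 0.16, 0.11 and -0.23 in wild type no stress libraries 1 to 4. In wild type heat shock libraries 1 to 4 they correlated at 0.06, -0.04, -0.14 and 0.02. A fall in translation on heat shock stays open and cannot be separated here from the change in footprint composition that came with it.

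In wild type no stress RNA library 1 the 10 highest genes took 20.7% of counts and Mettl14 stood at 30.5 CPM by total counts, each far from the other 3 libraries. In wild type recovery RNA library 4 mitochondrially encoded genes took 2.56% of counts, far from the other 3. Of 42 groups tested in this way 3 were beyond the limit and 2.1 would be by chance, which is 1 in 20. In data outside the main counts, 99.6% of stranded reads at Xist lay on the opposite strand, where Tsix is transcribed (38653 against 171; 5.65% over all genes). Knockout no stress footprint library 4, outside the comparisons, held 52.9 CPM of Mettl14 (5 of 94531 footprints, 17.2 to 123), against 3.13 CPM in libraries 1 to 3 (1 of 319128).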

How the results depend on the processing

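Chosen after seeing the data were the covariate, strand-specific counts, the title numbers, and the sets without 3 libraries or 4 samples. Counts of calls are given with genes up and down in parentheses; where a count changes below, the cause was not tested.

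For RNA, wild type heat shock against no stress (0) gave 9 by DESeq2, 80 with the share of reads outside genes as a covariate, 330 in title numbers 1 and 2, 2321 in 3 and 4, and 122 without the 3 libraries that stand apart in reads outside genes; it was 0 without any replicate. Wild type recovery against no stress (63) gave 209 by DESeq2, 12 with only the compared groups, 462 with the covariate, 95 with strand-specific counts, 32 in numbers 3 and 4, 217 without the 3 libraries, and 12 to 47 without a replicate. Recovery against heat shock (8) gave 101 by DESeq2, 2 with no filter, 16 with the compared groups, 0 with a replicate block, 329 with the covariate, 15 strand-specific, 1248 in numbers 1 and 2, 61 in 3 and 4, 0 with total counts, 262 without the 3 libraries, and 0 to 14 without a replicate. Knockout heat shock against no stress (22) gave 280 by DESeq2, 40 with no filter, 2432 with the compared groups, 182 with the covariate, 1104 in numbers 1 and 2, 88 in 3 and 4, 14 with total counts, 1104 without the 3 libraries, 80 without the 4 wild type samples, and 0 to 16 without a replicate. Knockout recovery against no stress (14) gave 577 by DESeq2, 6 with DESeq2's size factors, 8 with no filter, 5 with the compared groups, 81 with a replicate block, 427 with the covariate, 2 strand-specific, 1341 in numbers 1 and 2, 7988 in 3 and 4, 8 with total counts, 181 without the 3 libraries, 118 without the 4 samples, and 1 to 626 without a replicate.

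Knockout against wild type without stress (3594) gave 6252 with the covariate, 6277 without the 3 libraries, 2086 without the 4 samples and 2604 to 3680 without a replicate. After heat shock (2242) it gave 4441, 5014 and, without a replicate, 1600 to 2018, and was within 1.5 times without the 4 samples (2044). At recovery (3970) it gave 1145 with the compared groups, 10292 in numbers 3 and 4, 1648 without the 4 samples and 2718 to 5691 without a replicate. DESeq2, DESeq2's size factors, total counts, no filter, a replicate block, strand-specific counts and numbers 1 and 2 alone kept these 3 counts within 1.5 times. The interaction at heat shock (0) gave 40 in numbers 3 and 4 and 0 without any replicate. That at recovery (116) gave 547 by DESeq2, 75 with DESeq2's size factors, 60 with no filter, 3 with the compared groups, 849 with the covariate, 293 in numbers 1 and 2, 2117 in 3 and 4, 37 with total counts, 1115 without the 3 libraries, 0 without the 4 samples, and 10 to 226 without a replicate.

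Footprints of wild type heat shock (0) gave 955 by DESeq2, 684 with DESeq2's size factors, 94 with no filter, 118 with the compared groups, 118 with a replicate block, and 0 to 455 without a replicate. Wild type recovery (0) gave 22 with no filter and 0 without a replicate. Knockout against wild type without stress (0) gave 1 by DESeq2, 1 with DESeq2's size factors and 51 with no filter. It gave 7 with a replicate block, 1 with total counts and 0 to 1 without a replicate. At recovery (0) it gave 19 with no filter and 0 without a wild type replicate. Median shifts of all genes with TMM, DESeq2's size factors and total counts were -0.06, 0.77 and -0.23 at wild type recovery, 0.12, -0.51 and -0.18 between genotypes without stress, and -0.09, -1.86 and -0.04 at recovery.

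Translational efficiency in wild type heat shock (611) gave 1188 by DESeq2, 1012 with DESeq2's size factors, 248 with all 24 libraries, 401 with limma voom, 3011 with no filter, 155 with the compared groups, 0 with a block per sample, 5 without libraries under 0.25 of the median total, and 159 to 945 without a replicate. At wild type recovery (1) it gave 0 with DESeq2's size factors, all 24 libraries, limma voom, no filter, the compared groups, a block per sample, total counts or without the shallow libraries, and 0 to 2 without a replicate. Knockout against wild type without stress (0) gave 2 by DESeq2, 1 with DESeq2's size factors and 6 with no filter. It gave 1 with total counts and 0 to 13 without a replicate. After heat shock (0) it gave 8 by DESeq2, 1 with DESeq2's size factors, 1 with the compared groups and 0 to 193 without a replicate. At recovery (1) it gave 158 by DESeq2, 0 with DESeq2's size factors, 46 with all 24 libraries and 6 with limma voom. It gave 41 with no filter, 2 with total counts and up to 36 without a wild type replicate. It was 0 there with the compared groups, a block per sample, without the shallow libraries or without the 4 samples. Median shifts were 0.01, 0.53 and -0.13 at wild type recovery, 0.07, -0.53 and -0.20 between genotypes without stress, 0.53, 0.48 and 0.38 after heat shock, and -0.10, -1.65 and -0.19 at recovery.

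Of the named genes, 3766 results under alternatives gave 3282 on the same side of the threshold, 480 no longer past it, and 4 of opposite sign. Krt18 at recovery between genotypes turned in title numbers 1 and 2 (-0.023, adjusted p = 0.96). Mettl14 in knockout recovery against no stress, which was not called, turned in title numbers 1 and 2 (-0.028), without the 3 libraries (-0.072) and without recovery replicate 4 (-0.064, against up to 0.1599 without another replicate). Of 824 list results under alternatives 629 were the same, 185 no longer passed and 10 reversed, of which 1 passed: histones in knockout recovery against no stress without the 3 libraries (Down, 7.92e-06). The other 9 did not pass. With the share of reads outside genes as a covariate these were histones in knockout recovery (adjusted p = 0.45) and heat shock (0.85) against no stress. Without the 3 libraries they were the integrated stress response (0.79), trophoblast (0.79) and naive pluripotency (0.91) lists in knockout recovery against no stress. In the interaction of genotype and recovery they were glycolysis and hypoxia (0.44), histones (0.37), the integrated stress response (0.74) and oxidative stress (0.74). With an estimated correlation 1 of 99 list calls passed. Footprint depth limits what can be called: at the depth of wild type heat shock edgeR recovered 0% of simulated 4-fold footprint changes.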

Other observations

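The structure of the RNA libraries was examined by other splits of the samples, planned before the counts were known, and only the counts within title numbers were chosen after the result was seen.

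Besides the groups compared, the first 4 principal components of the RNA libraries hold 49.7, 16.8, 13.7 and 5.65% of the variance. Kdm5d and Eif2s3y were higher in the knockout in all 3 states, and Eif2s3y stood at 6.55, 5.50 and 5.72 CPM in wild type against 85.6, 88.6 and 66.4 CPM in the knockout, so the wild type and knockout lines also differ in Y-linked expression. Over 517 X-linked genes the median was 0.31, 0.24 and 0.29 higher in the knockout in the 3 states, and the genotype comparisons hold any other difference between the lines.

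For the comparisons of RNA, the labelled split called the most genes of 35 for wild type recovery against heat shock (8, highest other 6). It did so too for knockout heat shock (22, highest other 0) and recovery (14, highest other 3) against no stress. The same held for the genotypes without stress (3594, highest other 0). A share of 1 in 35 is the lowest such splits can reach, and several comparisons were made. For the 8 genes chance is not excluded, with 6 in another split and 0 left by a replicate block or total counts. The labelled split was also the largest of 35 for the genotypes after heat shock (2242) and at recovery (3970), where other splits called up to 453 and 2682 genes. The highest other at heat shock follows title numbers 1 and 2 against 3 and 4, within which 2223 and 1832 genes were called. Of the 8 splits that part all 4 pairs no other called any, though a share among them cannot fall below 1 in 8. Where 0 genes were called, all splits gave as many: 35 for wild type heat shock against no stress (highest other 0), 100 for the interaction at heat shock (highest other 34), 35 for footprints of wild type heat shock (highest other 4), wild type recovery (29) and the genotypes without stress (16), and 35 for translational efficiency of the genotypes without stress (80) and after heat shock (562), so that some splits call many genes and point to a structure of the samples. For translational efficiency at wild type recovery chance cannot be excluded (1 gene, 14 of 35 splits as large, highest other 50). Comparisons of the genotypes at recovery in footprints and translational efficiency have 2 knockout libraries and were not split.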
